A study of Ovis aries with 16 samples.

How the data were processed

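Lung RNA of 16 lambs was measured on 16 arrays, 8 from control lambs and 8 from lambs with a shunt. Per the labels' protocols, fetal surgery 9 ± 6 days before term was either a sham operation or the placement of a vascular graft, 8.0 mm wide and 2 mm long, between the ascending aorta and the main pulmonary artery, and peripheral lung was taken 3 days after spontaneous delivery. Per the labels' protocols, RNA was isolated with a column kit and biotin-labelled cRNA was made from 1 ug of total RNA. The probe sets carry bovine identifiers, so sheep cRNA was hybridized to bovine probes, and a sequence difference between the species or between lambs can lower a signal without a change in RNA.

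The authors deposited 1 log2 value per probe set and array, made with RMA per the submitters' processing notes. RMA subtracts background, normalizes the arrays to each other by quantiles and summarizes the probes of a probe set, and its version is not given in the sources used here. Scanner files and detection calls were not used here, so no level can be set against background. For arrays of this kind the number of arrays limits the precision. No scan date or hybridization batch was known, so batches could not be tested. Array medians and poly-A control levels differed between the groups, and a difference in processing between the groups cannot be excluded for any comparison of shunt with control. The labels describe no lamb individually, and each array was taken as 1 lamb. If arrays shared an animal, p-values would measure only the spread between arrays.

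The table held 24128 probe sets. The 112 control probe sets of the manufacturer were left out of all tests, which left 24016. The platform annotation gave 1 gene symbol for 13292 of them, several for 86 and none for 10638. Probe sets with several symbols or none were tested as probe sets and not named. For tests by gene, each of 9155 genes was represented by the probe set with the highest mean over all 16 arrays, and 2913 genes had more than 1 probe set. Of these gene symbols, 8498 were also found in a table of sheep genes. Positions in the genome were not used here, because the probe sets and that table belong to different species.

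Groups were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes, no covariate, a two-sided moderated test and Benjamini-Hochberg adjustment at a threshold of 0.05. Differences are log2 level in shunt minus control, with the standard error of the fit. Before the data were examined, 24 gene lists and 21 lists of cell type markers were fixed, with 918 genes, of which 673 were measured. The 40 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over the 40 lists, and again with a correlation estimated for each list, with fry, and with an exact two-sided permutation test of the list mean over the 12870 divisions of the lambs. The remaining 5 lists, of pericytes, ciliated cells, mast cells, platelets and mesothelium, had too few measured genes.

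Genes were named by a rule fixed at the same time. It took up to 12 genes per direction past the threshold, filled to 10 with the genes of smallest p where fewer than 10 passed, up to 4 members of smallest p from each list discussed, and 12 genes whatever their values (VEGFA, KDR, FLT1, ANGPT1, ANGPT2, TEK, FGF2, BIRC5, NOS3, EDN1, THBS1 and HIF1A). FGF2, ANGPT2 and BIRC5 were remembered as genes that the published study followed up from these arrays, so their values and the lists that hold them are not independent of it.

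The fits were tested on simulated data for the comparison of shunt with control, with the mean and spread of the real 9155 genes and 200 genes changed. Of 67 genes changed by 0.3, 34 were recovered (50.7%). Of 67 changed by 0.6, 65 were recovered (97.0%), and of 66 changed by 1 on the log2 scale, 65 were recovered (98.5%). Among the unchanged genes, 9 were called. Camera called a simulated list of 20 genes shifted by 0.15 and did not call one with no shift. The simulated genes varied independently of each other, which real list members do not. The Benjamini-Hochberg cutoff on p loosens as more genes pass, and only 8 genes passed in the real fit. The simulated fit held 200 changed genes, so its recovery can be higher than that in the real data.

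Alternatives fixed before the data were examined were a block for the replicate number, a filter on dim probe sets, quantile normalization again, centring on array medians, array weights, a trended and robust prior, the XIST level as a covariate for sex, other rules for the probe set of a gene, a threshold of 0.10, the other list tests, and each array left out in turn. Cyclic loess normalization, the 3' minus 5' difference of 5 control genes as a covariate, and the exact permutation as a list call were added after seeing the data. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.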

Results

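Gene expression was measured in peripheral lung of 3-day-old lambs, 8 with an aortopulmonary shunt placed before birth and 8 controls. The shunt sends aortic blood into the pulmonary artery and serves as a model of congenital heart disease with increased pulmonary blood flow. The comparison asked which genes, and angiogenic genes in particular, differed at this age. No measure of vessel structure was used here. The arrays were alike, with correlations between pairs from 0.980 to 0.995. Control replicate 2 stood apart, with a mean correlation of 0.983 with the other 15 arrays and the lowest array weight, 0.23. The 3' minus 5' difference of 5 control genes, a sign of RNA quality, was 1.84 ± 0.23 (SD) in control and 1.84 ± 0.15 in shunt lambs (n = 8 each, exact permutation p = 0.98). Array medians were 7.158 ± 0.016 in control and 7.135 ± 0.009 in shunt (exact permutation p = 0.00078). The poly-A control probe sets also differed, at 4.39 ± 0.08 in control and 4.31 ± 0.02 in shunt (exact permutation p = 0.00109), and still did without control replicate 2 (control mean 4.36, exact permutation p = 0.00171). Such levels are in the dimmest part of the arrays, where IGFBP2 at a mean of 5.89 was at percentile 11.5 of the genes, and signal over background is unknown there.

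Genes that rose in shunt lung included a subunit of the nitric oxide receptor, an endothelial receptor and an enzyme that edits heparan sulfate. SCARA5, a scavenger receptor, rose the most among the genes with a symbol that passed, by 0.84 ± 0.13 (SE, adjusted p = 0.0129), or 1.79-fold. ADGRL4, an adhesion G protein-coupled receptor of endothelial cells, rose by 0.54 ± 0.09 (adjusted p = 0.0340). OTULINL rose by 0.47 ± 0.07 (adjusted p = 0.0129), AFAP1L2, an adaptor protein in Src signalling, by 0.39 ± 0.07 (adjusted p = 0.0394), GUCY1B1, the beta subunit of soluble guanylate cyclase, by 0.37 ± 0.06 (adjusted p = 0.0340), and SULF2, an extracellular sulfatase, by 0.37 ± 0.06 (adjusted p = 0.0183). Each of these 6 genes lay above the control mean in 8 of 8 shunt lambs. TST, a mitochondrial sulfurtransferase, fell by 0.48 ± 0.09 (adjusted p = 0.0394) and lay below the control mean in 7 of 8 shunt lambs, the exception being shunt replicate 1. Another TST probe set differed by -0.06. ZNF821 fell by 0.26 ± 0.05 (adjusted p = 0.0486) in 8 of 8. SULF2, at a mean of 6.70 (percentile 22 of the genes), and ZNF821, at 6.44 (percentile 18), were dim. With the dim probe sets removed 6 of the 8 genes still passed.

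**Figure D1:**
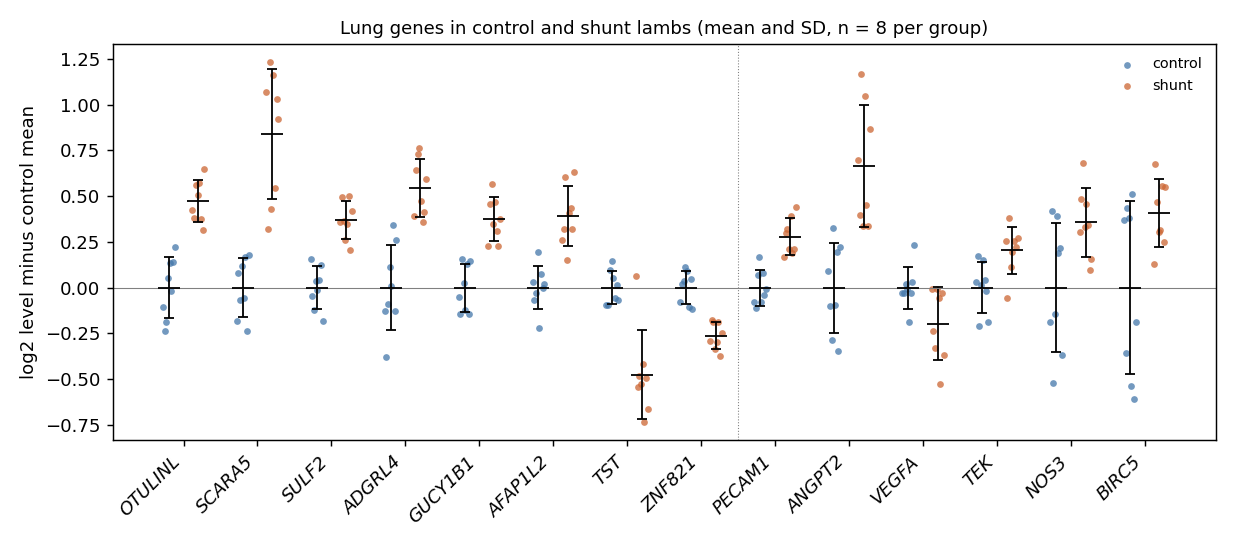
Level of 14 genes in each lamb as log2 minus the control mean, with controls in blue, shunt lambs in orange, and bars for the mean and SD of 8 lambs. The 8 genes left of the dotted line passed the test and the 6 on the right did not, and ANGPT2 has a mean difference of 0.66.

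These 6 genes higher and 2 lower in shunt were all that passed among 9155, while 1332 genes had an unadjusted p under 0.05, 607 higher and 725 lower, where 458 would be expected by chance. With each array centred on its median, 8 genes passed higher and 0 lower, and 849 were higher and 448 lower at an unadjusted p under 0.05. Among single probe sets, 16 were higher and 1 lower. Of these 17, 7 had no gene symbol, among them the largest difference of the 17, 0.99 ± 0.13 (SE, adjusted p = 0.00532), and probe sets of ACTG1 (0.28), SEPTIN8 (0.39) and PECAM1 (0.35) passed that did not represent their genes. The count of genes moved with single arrays. It was 64 without shunt replicate 1 and 13 without control replicate 6. It was 2 without control replicate 5, shunt replicate 3 or shunt replicate 8, 3 without control replicate 1, control replicate 7 or shunt replicate 5, 4 without shunt replicate 2 or 6, and 5 without control replicate 2 or 3 or shunt replicate 4. OTULINL and SCARA5 passed in 16 of 16 such fits, SULF2 in 13, ADGRL4 in 7, GUCY1B1 in 6, AFAP1L2 in 4, ZNF821 in 3 and TST in 2. Probe sets ranged from 6 to 53 higher and from 0 to 22 lower, with the most in both directions without shunt replicate 1.

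The genes next in order did not pass. On the higher side they were FLI1, an ETS transcription factor of endothelium and blood cells (0.39 ± 0.07, adjusted p = 0.0519), PHF6 (0.36 ± 0.07, adjusted p = 0.0559), PECAM1, an adhesion molecule of endothelial cells (0.28 ± 0.05, adjusted p = 0.0559), and the growth factor binding protein IGFBP2 (0.70 ± 0.14, adjusted p = 0.0559). On the lower side were the AP-1 subunit JUN (-0.27 ± 0.05, adjusted p = 0.0522), GTF3C1 (-0.22), the gluconeogenic enzyme FBP1 (-0.53), CHCHD6 (-0.24), UNC119 (-0.30), TRAF4 (-0.24), PEBP4 (-0.56) and STXBP2 (-0.30), with adjusted p from 0.0559 to 0.0935. Another probe set of PHF6 differed by -0.10.

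The angiopoietin and TIE list, which holds ligands and receptors that control vessel stability, was shifted higher (mean difference 0.16, 5 of 7 genes in that direction, camera adjusted p = 0.0256). With an estimated correlation the adjusted p = 0.372. ANGPT2, a ligand of the receptor TEK, was 9.18 ± 0.25 (SD, n = 8) in control and 9.85 ± 0.33 in shunt, a difference of 0.66 ± 0.13 (SE) above the control mean in 8 of 8 lambs that missed the threshold over all genes (adjusted p = 0.0559). TEK differed by 0.20 ± 0.07 (adjusted p = 0.228), ANGPT4 by 0.17, TIE1 by 0.17 and ANGPT1 by 0.05 ± 0.19. Adjusted over the list alone, 2 genes passed, ANGPT2 and TEK. This list is not independent of the published study, which followed up ANGPT2. The call held in 14 of 16 fits with 1 array left out, with the highest adjusted p, 0.0727, without control replicate 3, and was lost without the dim probe sets (adjusted p = 0.0741, angiopoietin and TIE).

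VEGF and PlGF ligands and receptors showed no shift (mean 0.02, 6 of 10 genes higher, camera adjusted p = 0.512). VEGFA, the main endothelial growth factor, was -0.20 ± 0.08 (adjusted p = 0.277), its receptors KDR and FLT1 were 0.08 ± 0.08 and 0.04 ± 0.07, NRP2 was 0.13 and PGF 0.14. Other probe sets had the opposite sign for KDR (-0.09), FLT1 (-0.07 and -0.11) and NRP2 (-0.23). The KDR probe set was dim, at a mean of 6.05 (percentile 13.2 of the genes), and signal over background is unknown there. Its small difference does not show that KDR was unchanged. The fibroblast growth factor list had a mean of -0.13 with 2 of 8 genes higher (camera adjusted p = 0.180), with FGFR4 at -0.40 ± 0.13, FGFR2 at -0.37 ± 0.14, FGFR3 at -0.13 and FGF10 at 0.06. By exact permutation this list had p = 0.0146 (adjusted p = 0.132). Over 14 alternatives its mean ran from -0.16 to -0.05, and it passed in 0. Another FGFR2 probe set was at 0.0060 and another of FGF10 at -0.05. FGF2 depended on the probe set. The brighter one, which represents the gene, was 10.49 ± 0.26 (SD, n = 8) in control and 10.39 ± 1.09 in shunt, and the dimmer one was 9.41 ± 0.24 and 9.92 ± 0.20, a difference of 0.51 ± 0.10 (SE, adjusted p = 0.0731 over probe sets). Shunt replicates 1 and 2 read 9.12 and 8.31 with the brighter probe set. Other angiogenic factors did not pass (mean 0.06, 18 of 31 higher, camera adjusted p = 0.166), with PTN at 0.64 ± 0.19, ENG at 0.32 ± 0.09, HIF1A at 0.20 ± 0.06 and the vasodilator peptide ADM at -0.64 ± 0.17. Adjusted over the list alone PTN, ENG and ADM passed. Without the dim probe sets this list was shifted higher (mean 0.11, adjusted p = 0.0281), the 1 of 14 alternatives in which it passed (adjusted p up to 0.372). Among angiogenesis inhibitors (mean 0.05, 14 of 22 higher, camera adjusted p = 0.0843) the collagen genes COL4A1 (0.22 ± 0.05) and COL15A1 (0.24 ± 0.06) passed adjusted over the list alone, COL18A1 was at 0.18 and IL12A at -0.34. THBS1 was at 0.26 ± 0.20, and another of its probe sets at -0.07. The inhibitor list passed as higher in 3 of 14 alternatives, without the dim probe sets (mean 0.16, adjusted p = 0.00418), with array weights (0.09, adjusted p = 0.00913) and after quantile normalization again (0.04, adjusted p = 0.0437), with adjusted p up to 0.619 in the others. With 1 array left out its mean ran from 0.021 to 0.068, and it passed without control replicate 2 (adjusted p = 0.0134) or shunt replicate 1 (adjusted p = 0.0393) and had the highest adjusted p, 0.174, and the lowest mean without control replicate 4.

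**Figure D2:**
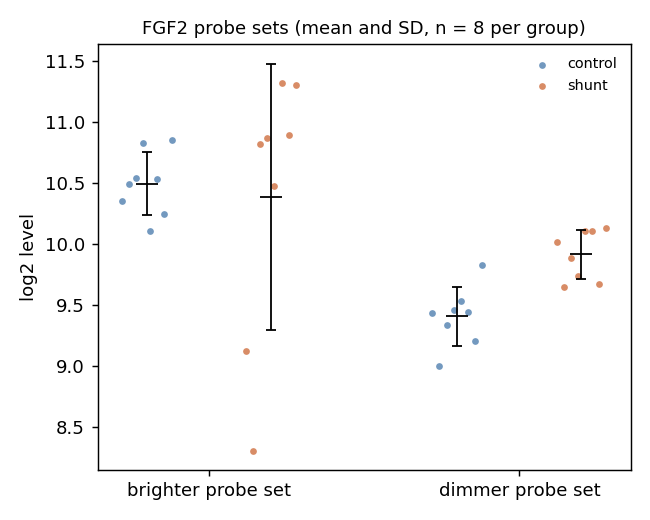
Log2 level of both FGF2 probe sets in each lamb, with controls in blue, shunt lambs in orange, and bars for the mean and SD of 8 lambs. With the brighter probe set 2 shunt lambs lie below all controls, at 9.12 and 8.31, and with the dimmer one the means are 9.41 and 9.92.

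In nitric oxide and cyclic nucleotide signalling 1 of 22 genes, GUCY1B1, passed over all genes, and 2 passed adjusted over the list alone, the other being the alpha subunit of the same enzyme, GUCY1A1 (0.49 ± 0.12). NOS3, the endothelial nitric oxide synthase, was at 0.36 ± 0.13 (adjusted p = 0.245) and ASS1 at 0.27. The list as a whole did not pass by camera (mean 0.07, camera adjusted p = 0.144). By exact permutation it had p = 0.0115 (adjusted p = 0.132). Endothelin and vasoconstrictor genes had a mean of -0.04 (8 of 17 higher, camera adjusted p = 0.660), with EDN1 at 0.30 ± 0.24, EDN3 at -0.52 ± 0.24, AGTR2 at -0.15 (another probe set at 0.11), SLC6A4 at -0.12 and ROCK2 at 0.11.

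Markers of vessel wall cells were shifted higher. Smooth muscle markers had a mean difference of 0.17 (8 of 10 higher, camera adjusted p = 0.00411, with an estimated correlation adjusted p = 0.372), and the contractile genes MYH11 (0.33 ± 0.11), TPM2 (0.37 ± 0.12) and TAGLN (0.39 ± 0.14) passed adjusted over the list alone, with ACTA2 at 0.27. Another TPM2 probe set was at -0.05. Endothelial markers had a mean of 0.11 (10 of 13 higher, camera adjusted p = 0.0124, with an estimated correlation adjusted p = 0.372), and PECAM1, ENG and TEK passed adjusted over the list alone, with EMCN at 0.22. Shear-responsive endothelial genes had a mean of 0.12 (14 of 18 higher, camera adjusted p = 0.00599, with an estimated correlation adjusted p = 0.372), led by PECAM1 and ANGPT2, with ADM in the other direction. In these 3 lists 0 genes passed over all genes (limma), while each had 5 genes higher at an unadjusted p under 0.05, and the shear-responsive list 1 lower. The endothelial markers share 2 genes with the shear-responsive list and 2 with the angiopoietin and TIE list.

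**Figure D3:**
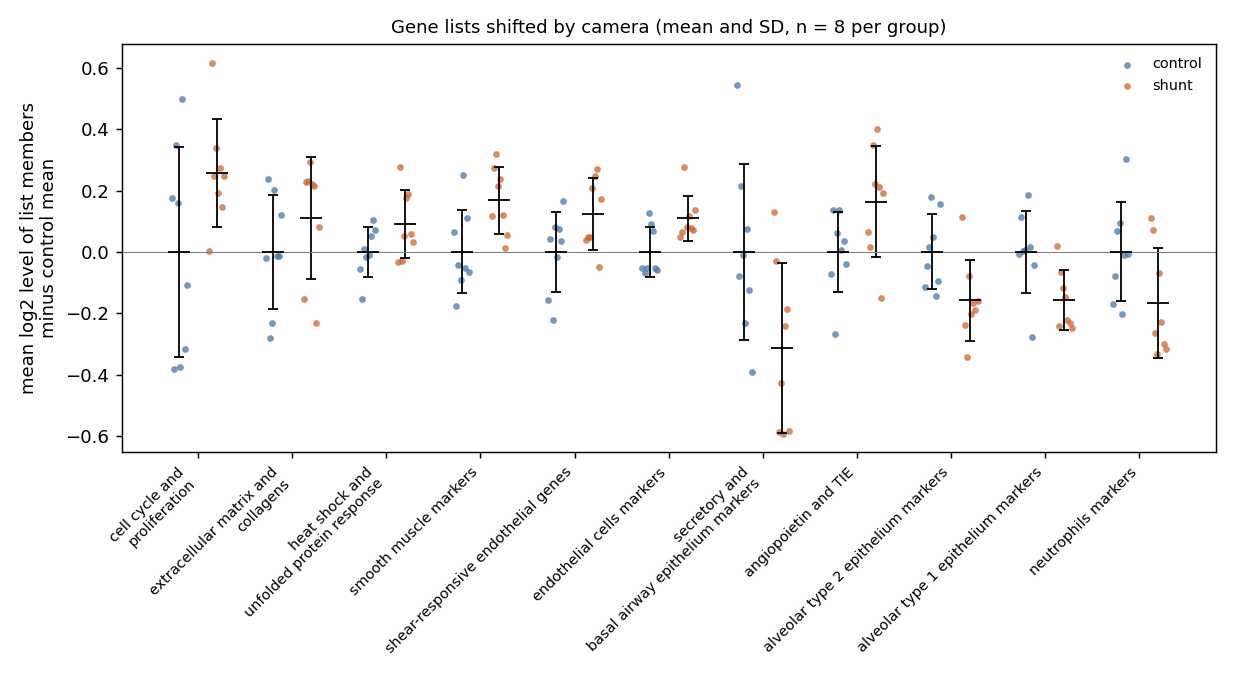
Mean log2 level of the members of the 11 shifted lists in each lamb, minus the control mean, with controls in blue, shunt lambs in orange, and bars for the mean and SD of 8 lambs. Smooth muscle markers lie higher by 0.17 and alveolar type 2 markers lower by 0.16 in shunt lambs, and the groups overlap in each list.

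Cell cycle genes had the smallest p of the lists, with 36 of 41 genes higher and a mean difference of 0.26 (camera adjusted p = 2.7e-07). The members moved together from lamb to lamb, with an estimated correlation of 0.54, and with it the adjusted p = 0.392. None passed adjusted over the list alone (limma), and 16 were higher and 1 lower at an unadjusted p under 0.05. The mitotic genes NUSAP1 (0.72 ± 0.26), HMMR (0.47 ± 0.18) and KIF23 (0.44 ± 0.16) and the survivin gene BIRC5 (0.41 ± 0.16, adjusted p = 0.268) were among them, and the cyclin gene CCND1 was at -0.33 ± 0.11. The extracellular matrix list (mean 0.11, 21 of 27 higher, camera adjusted p = 0.00411, with an estimated correlation adjusted p = 0.432) was led by COL4A1 and the elastin gene ELN (0.48 ± 0.11), both past the threshold adjusted over the list alone, with FBLN5 at 0.38 and LUM at 0.60. Another ELN probe set was at -0.02. Its mean was 0.19 with array weights and 0.07 without control replicate 3 (adjusted p = 0.0375). Heat shock and unfolded protein response genes (mean 0.09, 23 of 27 higher, camera adjusted p = 0.00411, with an estimated correlation adjusted p = 0.372) included HSPA5 (0.22 ± 0.07), CANX (0.17), HSPH1 (0.38) and DNAJA1 (0.26), none past the threshold adjusted over the list alone.

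Epithelial markers were shifted lower. Alveolar type 2 markers had a mean difference of -0.16 (0 of 8 higher, camera adjusted p = 0.0297, with an estimated correlation adjusted p = 0.372), with the surfactant genes SFTPB at -0.23 ± 0.09 and SFTPC at -0.15 ± 0.07, the phosphate transporter SLC34A2 at -0.34 ± 0.14 and the lipid transporter ABCA3 at -0.19. Alveolar type 1 markers had a mean of -0.16 (1 of 6 higher, camera adjusted p = 0.0469, with an estimated correlation adjusted p = 0.372), with the water channel AQP5 (-0.26 ± 0.06) past the threshold adjusted over the list alone, CLIC5 at -0.34, PDPN at -0.19 and AGER at -0.15. Secretory and basal airway markers had a mean of -0.31 (0 of 6 higher, camera adjusted p = 0.0171, with an estimated correlation adjusted p = 0.372), with TFF3 at -0.63 ± 0.23, BPIFA1 at -0.26, KRT14 at -0.24 and KRT15 at -0.15. Neutrophil markers had a mean of -0.17 (0 of 8 higher, camera adjusted p = 0.0469, with an estimated correlation adjusted p = 0.372), with ELANE at -0.24, MPO at -0.17, CAMP at -0.12 and MMP9 at -0.29. With 1 array left out the calls held in 12 of 16 fits for type 2 markers (highest adjusted p 0.121, without control replicate 8), 6 for type 1 (0.0983, without shunt replicate 2), 15 for airway (0.0907, without control replicate 1) and 7 for neutrophil markers (0.118, without control replicate 7). The neutrophil list also lost its call after quantile normalization again (adjusted p = 0.0796), with the mean of a gene's probe sets (0.0876) and after cyclic loess (0.0675), and the type 1 list with array weights (0.0505). Surfactant and fluid transport genes, with 3 of 18 higher and a mean of -0.09, did not pass (camera adjusted p = 0.0862), and AQP1, a water channel of endothelium, was at 0.33 ± 0.10 there, with another probe set at -0.03. That list passed as lower in 5 of 14 alternatives, without the dim probe sets (adjusted p = 0.0408), after quantile normalization again (0.0437), with array weights (0.0217), with the most variable probe set (0.0374) and after cyclic loess (0.0311), with adjusted p up to 0.417 in the others. With 1 array left out it passed without control replicate 7 (adjusted p = 0.0259) or shunt replicate 1 (adjusted p = 0.00801) and had the highest adjusted p, 0.199, without control replicate 8.

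In all, 11 of 40 lists were shifted, 7 higher and 4 lower, and 7 were without control replicate 8. With an estimated correlation 0 were, and by fry 0, while 2 and 14 lists had an unadjusted p under 0.05. By exact permutation of the lambs 0 lists passed after adjustment and 9 had an unadjusted p under 0.05. The difference between groups moved with level, from a median of -0.036 in the dimmest 10% of genes to 0.023 in the brightest 10%.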

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

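A single lamb far from the rest of its group, by the gap to its neighbour over the range of the group of 8, was found for 17 of 280 sets of values (103 genes, 23 lists and 14 array measures in both groups), where chance gives about 14. Of the 17, 8 were control replicate 2.

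Control replicate 2 was apart in the mean correlation with the other arrays (0.983 against 0.990 to 0.993, ratio of gap to range 0.776), in the spread of its values around the median array (0.373 against 0.139 to 0.225, ratio 0.634) and in the level of the poly-A control probe sets (4.58 against 4.32 to 4.42, ratio 0.630). It also had the highest ELN (11.71, ratio 0.627) and COL18A1 (5.01, ratio 0.542) and the lowest CANX (11.15, ratio 0.546), C1QB (8.78, ratio 0.567) and macrophage marker mean (-0.36, ratio 0.651) of the controls.

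Shunt replicate 1 had the highest TST (11.83 against 11.03 to 11.35, ratio 0.602), ABCA3 (10.07, ratio 0.604) and surfactant and fluid transport mean (0.13 against -0.16 to -0.07, ratio 0.694) and the lowest PGF (6.89, ratio 0.554) of the shunt lambs. The other lone values were MSR1 in shunt replicate 2 (9.08, ratio 0.576), the endothelial marker mean in shunt replicate 3 (0.28, ratio 0.616), the VEGF and PlGF mean in control replicate 5 (0.15, ratio 0.552), ROCK2 in control replicate 6 (above 10.56 to 10.76 in the others, ratio 0.562) and the fibroblast growth factor mean in control replicate 6 (-0.13, ratio 0.682).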

How the results depend on the processing

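Cyclic loess, the 3' minus 5' covariate and the permutation as a list call were chosen after seeing the data. The 8 genes that passed kept their direction in 222 of 222 combinations with an alternative, and the 11 shifted lists kept their direction throughout. For genes, direction could not turn under the looser threshold, the replicate block or the trended prior, which leave the differences unchanged. The genes stayed past the threshold of the alternative in 140 combinations. That count includes the looser threshold, which all 8 genes pass by construction. Signal over background is unknown here. The cause was not tested for any of the following values, except that leaving out an array lowers the number of lambs.

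The arrays gave no sign that the replicate numbers pair the lambs: same-numbered arrays correlated from -0.26 to 0.22, 2 of 8 above 0.1, and 0 of 8 matched best. With the replicate number as a block, which lowers the residual degrees of freedom, 0 genes and 0 probe sets passed in either direction. Genes at an unadjusted p under 0.05 were 540 higher and 611 lower, against 607 and 725 without the block, and 11 lists were shifted.

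With the dim probe sets removed 2 probe sets were lower, and 445 genes were lower at an unadjusted p under 0.05. After quantile normalization again 9 probe sets were higher and 1 gene lower. With median centring 25 probe sets were higher, 0 genes lower and 448 genes lower at an unadjusted p under 0.05. Array weights gave 36 probe sets higher and 9 lower, 10 genes higher and 7 lower, and 17 lists. The trended prior gave 2 probe sets lower. The XIST covariate gave 4 probe sets lower, 10 genes higher and 6 lower. At 0.10, 44 probe sets were higher and 11 lower, and 15 genes higher and 11 lower. With the most variable probe set 0 genes were lower, against 720 at an unadjusted p under 0.05. Cyclic loess gave 1 gene lower, and the 3' minus 5' covariate 34 probe sets higher and 7 lower, and 11 genes higher and 8 lower. With an estimated correlation, fry or permutation, 0 lists were shifted. Without the dim probe sets the airway and neutrophil lists had too few genes for a test.

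Leaving out single arrays gave 6 to 53 probe sets higher and 0 to 22 lower, 2 to 30 genes higher and 0 to 34 lower (the most without shunt replicate 1), 463 to 699 genes higher and 568 to 891 lower at an unadjusted p under 0.05, and 7 to 15 lists.

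Direction turned for the following values. With the mean of a gene's probe sets KDR was -0.0026, FLT1 -0.045, NRP2 -0.053, FGF2 0.20 and the VEGF and PlGF list -0.011. With the most variable probe set FLT1 was -0.11, NRP2 -0.23 and the VEGF and PlGF list -0.024. With single arrays left out FGF2 ran from -0.24 to 0.19 and ANGPT1 from -0.050 to 0.17. The endothelin list turned by its test with array weights (mean -0.0029) and ran from -0.051 to -0.010. The macrophage list, whose mean (0.011) and test differ in sign, turned with the block (0.011), the dim filter (0.039), the most variable probe set (0.0099), the 3' minus 5' covariate (0.010) and the permutation (0.011), and ran from -0.041 to 0.043.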

Other observations

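The tests of explanations below were chosen after the results were seen, while the counts over other divisions of the lambs were set before theirs were computed. Taking the larger direction of each other division, and reading the counts by the highest other division, were chosen later.

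The carnitine and fatty acid metabolism list, which holds genes of fatty acid oxidation, synthesis, uptake and regulation, had a mean of -0.05 with 9 of 34 higher and did not pass (camera adjusted p = 0.120, with an estimated correlation adjusted p = 0.372). It passed as lower in 3 of 14 alternatives, after quantile normalization again (adjusted p = 0.0316), with array weights (0.0489) and after cyclic loess (0.0311), with adjusted p up to 0.502 in the others, and without shunt replicate 1 (adjusted p = 0.0302). With 1 array left out its mean ran from -0.073 to -0.032, with the highest adjusted p, 0.265, without shunt replicate 2. ACADVL, which starts the oxidation of long-chain fatty acids, was at -0.20 ± 0.05 (SE) and passed adjusted over the list alone, CRAT was at -0.15 ± 0.04, HADHA at -0.22 ± 0.08 and ACADM at 0.11. The largest differences of any gene, chosen here after their values were seen, were UCP3 at -1.16 ± 0.26 (adjusted p = 0.0936), a mitochondrial carrier of muscle, and AGR2 at -1.15 (adjusted p = 0.441), a gene of mucous cells. Hypoxia response genes were not shifted (mean -0.07, 8 of 26 higher, camera adjusted p = 0.255). EGLN1 was at 0.11 and PFKFB3 at 0.23 (other probe sets at -0.02, and at -0.07 and -0.15), while ADM and VEGFA were on the lower side.

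Inflammatory cytokines and chemokines had a mean of 0.10 (19 of 32 higher, camera adjusted p = 0.137). The interleukin-1 receptor genes IL1R2 (0.38 ± 0.13) and IL1R1 (0.21 ± 0.08) and the antagonist IL1RN (0.28 ± 0.10) were on the higher side and CCL3 at -0.20, none past the threshold. This list passed as higher in 3 of 14 alternatives, after quantile normalization again (adjusted p = 0.0437), with array weights (0.0291) and after cyclic loess (0.0484), with adjusted p up to 0.560 in the others, and without control replicate 2 (adjusted p = 0.0471). With 1 array left out its mean ran from 0.064 to 0.143, with the highest adjusted p, 0.254, without control replicate 5. Macrophage markers went both ways (mean 0.01, median -0.05, camera adjusted p = 0.968), with MSR1 at 0.50 ± 0.15 (another probe set at -0.14) and CD14 at 0.42 ± 0.15, and ITGAM at -0.10 and C1QB at -0.21. Genes of TGF-beta and BMP signalling did not pass (mean 0.04, 15 of 25 higher, camera adjusted p = 0.0543), with ENG, LTBP1 (0.30 ± 0.10) and BMPR2 (0.33 ± 0.12, another probe set at -0.04) higher in value and BMP7 at -0.30 ± 0.10. That list passed as higher in 3 of 14 alternatives, after quantile normalization again (adjusted p = 0.0437), with array weights (0.0217) and with the XIST covariate (0.0468), with adjusted p up to 0.525 in the others, and without control replicate 2 (0.0327), control replicate 5 (0.0178) or shunt replicate 8 (0.0213). Its mean ran from 0.025 to 0.071 over the fits with 1 array left out, with the highest adjusted p, 0.139, without control replicate 4.

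Of 100 divisions of the lambs into 8 and 8, the real one included, 1 gave 16 or more probe sets in one direction, where the highest of the others was 1, and 2 gave 1 or more, the count of lower probe sets, where the highest of the others was again 1. For genes, 1 division reached the 6 higher (highest other 3), 2 reached the 2 lower (highest other 3) and 2 reached 1332 genes at an unadjusted p under 0.05 (highest other 1351). Only the 16 probe sets and the 6 genes higher lay above every other division drawn, which argues against a chance division for them. Other divisions matched or exceeded the lower counts and the 1332 genes, so chance is not excluded there. Nor is it for the 11 shifted lists, since 11 of 100 divisions gave as many (highest other 17).

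Both vessel wall lists lay above and all 3 epithelial lists below the control mean in 7 of 8 shunt lambs and 0 of 8 controls, while in shunt replicate 1 the epithelial lists were also above it (0.02, 0.11 and 0.13). These lists and their directions were picked because camera called them in the same arrays, so the counts describe the pattern and give it no separate support. Taken singly, the lists had adjusted p from 0.132 to 0.188 by exact permutation. More airway in the control pieces would leave alveolar markers higher in shunt, and they were lower (mean -0.16, exact permutation p = 0.0095), which argues against it for the alveolar part. Both alveolar lists had already been called lower, so that p gives no separate support. Nor do the alveolar markers tell whether more airway in the control pieces gave the lower airway list in shunt. The shift between arrays that depends on level is argued against as well, since the mean of the vessel lists minus that of the epithelial lists was 0.35 ± 0.08 (SE) before and 0.34 ± 0.08 after cyclic loess. The exact permutation p of this contrast, 0.0014, is for lists picked for their directions and does not test the pattern anew. A lower share of epithelium would raise the markers of other types alike. The difference of shunt from control in endothelial markers exceeded that in T and NK cell markers by 0.18 ± 0.05 (adjusted exact permutation p = 0.0325 over 11 types, and 0.23 ± 0.06 with the members above the median level). T and NK cell markers were themselves lower in shunt (-0.07, exact permutation p = 0.0406). A fall of their own beside less epithelium would give the same gap, so the gap leaves the share of epithelium undecided. The 11 types were compared only after macrophage markers alone had not decided (0.10 ± 0.09, exact permutation p = 0.276, adjusted p = 0.434). Only 2 of the 11 types lay apart (the other being cartilage), and neutrophils did not (0.28 ± 0.10, adjusted p = 0.0534). The gap was 0.04 ± 0.15 for fibroblasts, 0.03 ± 0.11 for lymphatic endothelium and 0.02 ± 0.16 for erythroid cells, whose markers were higher in value by 0.07, 0.08 and 0.09. A lower share of epithelium, a change in the share of vessel cells, a change within cells under the shunt and a difference in processing between the groups stay open, and only the first was put to a test.

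The cell cycle list was higher by 0.26 ± 0.14 (SE) over lambs, with an exact permutation p of 0.078, so with its members moving together the lambs alone do not separate the groups. The level-dependent shift is argued against, since cyclic loess removed -0.0027 ± 0.0107 of the difference. That control replicate 2, the array that stands apart, carries most of it is argued against too, since leaving it out removed 0.054 of the difference, and control replicates 5 and 7 scored about as low (-0.37 and -0.32 against -0.38). More dividing cells in shunt lung remains a hypothesis with no test here.

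The FGF2 probe sets gave different answers, and the dimmer one was higher in value where the brighter one had 2 low shunt lambs. A sequence variant or transcript form that only one probe set reads could give this. Within groups the probe sets had a Pearson r of 0.30 (permutation p = 0.252) and a Spearman rho of 0.30 (permutation p = 0.252) over 16 lambs, and r was 0.34 without the 2 lambs farthest from the median of the dimmer probe set. The 95% interval of r, -0.27 to 0.72, holds both values expected of probe sets that read the same RNA and of probe sets that do not, so r leaves the explanation undecided. Being a measure over all 16 lambs, r does not address shunt replicates 1 and 2. These read 9.12 and 8.31 with the brighter probe set, below all controls (10.11 to 10.85), while the other shunt lambs read 10.48 to 11.32. The difference with the brighter probe set was -0.10 with all lambs, 0.08 without shunt replicate 1 and 0.19 without shunt replicate 2. Its sign thus rested on these 2 lambs. With the dimmer probe set shunt replicates 1 and 2 read 10.02 and 9.65, where controls ran from 9.005 to 9.832. The cause of these low readings was not tested, and no biological explanation of the disagreement was tested.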
